A study of Oryza sativa Japonica Group with 6 samples.

How the data were processed

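RNA was taken from endosperm 7 days after pollination, 3 libraries labelled wild type and 3 labelled nf-yc11, and grouped by the genotype in the labels. Per the labels' protocols, total RNA was extracted with TRIzol and libraries followed a standard Illumina protocol. The authors deposited 1 table of FPKM values with a column for each of the 6 libraries. Per the submitters' processing notes, the tools named were CASAVA 1.7, HISAT2 2.0.5 and DESeq, with no role or order. The counting tool, the genome build and the annotation are not given in the sources used here, so no coordinates are printed.

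The table held 93655 features, of which 36189 were above 0 in any library. Of the features, 37830 had RAP gene IDs and 53250 had IDs beginning with EPlOSAG. FPKM values divide the reads of a gene by its length and by the library's total, so whole reads could be searched for: they were recovered for 36189 of 36189 features, within 0.0001 of a whole number. The recovered reads summed to 99.6% to 99.7% of the totals behind the values. In simulated tables of 4000 genes the search returned the exact count for 99.1% of genes with reads. The floor of 3 reads on a gene of 1500 bases was 0.091 to 0.137 FPKM, which covers counting error only.

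Changes were tested with limma 3.58.1 in R 4.3.3 on log2(FPKM + 1), with the variance trend, over features with a mean of at least 1 FPKM in the 6 libraries and Benjamini-Hochberg adjustment. Fold changes on this log2(FPKM + 1) scale understate the change of low genes, whereas folds in words are ratios of mean FPKM. No change of scaling was made between libraries in the results first given. An exact permutation test of 3 against 3 libraries cannot go below p = 0.1, so the model over all features was used. Tested on simulated data for this comparison (21800 genes, 50 at each size), the test recovered 20% of genes at a log2 change of 0.3, 60% at 0.5, 80% at 1 and 86% at 2, with 7 false calls. Every simulated gene had the same spread above counting noise, a coefficient of variation of 1.88%, whereas the real spread differed between genes. Few simulated genes were changed, against 49.1% of features in the data. These rates and false calls therefore need not hold for the data. Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3 read the table, and matplotlib 3.10.9 drew the plots.

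Gene lists were tested with camera in limma, with a preset correlation between genes of 0.01, and Benjamini-Hochberg adjustment over the 12 lists with at least 5 tested members. Camera was repeated with a correlation estimated from the residuals, and fry, which asks whether a list's genes move on balance one way, was run beside it. None of the 12 lists was called with the estimated correlation, where 5 had an unadjusted p under 0.05, and fry called 10. A list of cytosolic ribosomal protein genes rested on gene descriptions and was not analysed here.

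The table pairs no ID with a name. Of 156 list genes, 140 IDs were written with their symbols, from general knowledge of rice genes, before the data were examined. The other 16, all photosynthesis genes, were added once the IDs but none of the values had been seen. The symbols were checked by chromosome and order of position against a RefSeq gene table of assembly ASM3414082v1, which holds no RAP IDs. There, 84 symbols were found, 78 in the place the ID gives, and 72 were not in it and rest on the written pairs alone, including NF-YC8, NF-YC9, NF-YC10, NF-YC11 and NF-YC12. 5 were dropped (CIN1, GluB7, GluC, Glb1 and P58B), and 3 IDs, that of NF-YC9 among them, were not used here.

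The genes named were set beforehand: the NF-Y genes, the 10 largest rises and 10 largest falls of at least 2-fold with non-overlapping groups and at least 5 FPKM in the higher group, and from each list the most abundant member and up to 3 with the smallest p. Only 2 IDs without a symbol are printed per direction. Outside this rule, 15 list members were named after their values were seen: AGPS2, SSIIIa, BEIIa, BEIIb, GBSSI, SUS1, GluB1a, GluA2, RP13b, RP13c, HSP17.4, LHCB6, ERO1, bHLH144 and RSR1. Values are also given for RAG1, whose list was too short to test, and Glb1, dropped by the name check. RAG1 and Glb1 were not followed through the alternatives as named genes.

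The alternatives set before the data were examined were another pseudocount (0.1), other filters (none, or 5 FPKM), size factors by the median of ratios, TMM factors, quantile normalization, no variance trend, a 2-fold minimum, the replicate number as a block, leaving out each library, the estimated correlation and fry. Added afterwards were voom on the recovered reads, RAP gene IDs only, the total without the 100 most abundant genes, a gene length trend removed, and other choices of list members.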

Results

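Gene expression was measured by RNA sequencing in rice endosperm, the starch-storing tissue of the grain, 7 days after pollination. The series title names ZH11, a japonica cultivar, and a mutant, nf-yc11, named for a subunit of the NF-Y transcription factor. There were 6 libraries, 3 labelled wild type (WT) and 3 labelled nf-yc11, and the design text sets the question as the mRNA levels of the mutant against the wild type. Values were FPKM, which relate the reads of a gene to its length and to the library's total. The read totals that the FPKM values were divided by, worked out from the values themselves, were 21984785, 15610548 and 14593215 in WT replicates 1 to 3. In nf-yc11 replicates 1 to 3 they were 15735968, 15953367 and 16989039. The reads recovered for the features summed to 99.6% to 99.7% of these totals. At these depths 1 read on a gene of 1500 bases was worth 0.0303 to 0.0457 FPKM. Gene symbols below were paired with feature IDs from general knowledge of rice genes before the data were examined, except where said. Of 156 symbols, 72 were not in the gene table and could not be checked. Among them were all the NF-YC and prolamin symbols, most photosynthesis symbols, and BEIIa, BEIIb, SSIIIa, PUL and PHOL.

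NF-YC11 itself (OS05G0304800) stood at 126 ± 3.07 FPKM (SD, n = 3) in the WT libraries and at 110 ± 3.35 FPKM in the libraries labelled nf-yc11. This is a fall of 1.15-fold (log2 change −0.20 ± 0.04 SE, adjusted p = 0.0037, limma). The largest fall among the NF-Y genes was that of another NF-YC gene, NF-YC12 (OS10G0191900), which dropped 3.93-fold from 755 ± 12.1 to 192 ± 1.41 FPKM (log2 change −1.97 ± 0.02, adjusted p = 1.92e-07, limma). NF-YB1 (OS02G0725900), an endosperm NF-YB subunit, fell 1.83-fold, from 439 ± 14.7 to 240 ± 4.42 FPKM. NF-YC8 fell from 22.2 ± 1.45 to 13.7 ± 0.637 FPKM and NF-YC10 from 46.8 ± 2.72 to 35.1 ± 1.64 FPKM. NF-YB9 rose from 52.5 ± 1.28 to 61.3 ± 5.17 FPKM (log2 change 0.22, adjusted p = 0.0251, limma). Its call ended under each scaling between libraries, with adjusted p of 0.0898 to 0.2, without the variance trend (0.0505), and without WT replicate 1 (0.0657) or WT replicate 3 (0.0743). As a list, the NF-Y genes had 5 members lower and 1 higher of 6 (median log2 change −0.53, adjusted p = 0.000888, camera in limma, and adjusted p = 0.0582 with an estimated correlation). The labels give no locus for the mutation, and the numbering of NF-YC genes is not uniform among sources. A mutation can leave its transcript in place, so these levels do not settle which NF-YC gene was altered, and the 3 libraries are called by their label throughout.

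**Figure D1:**
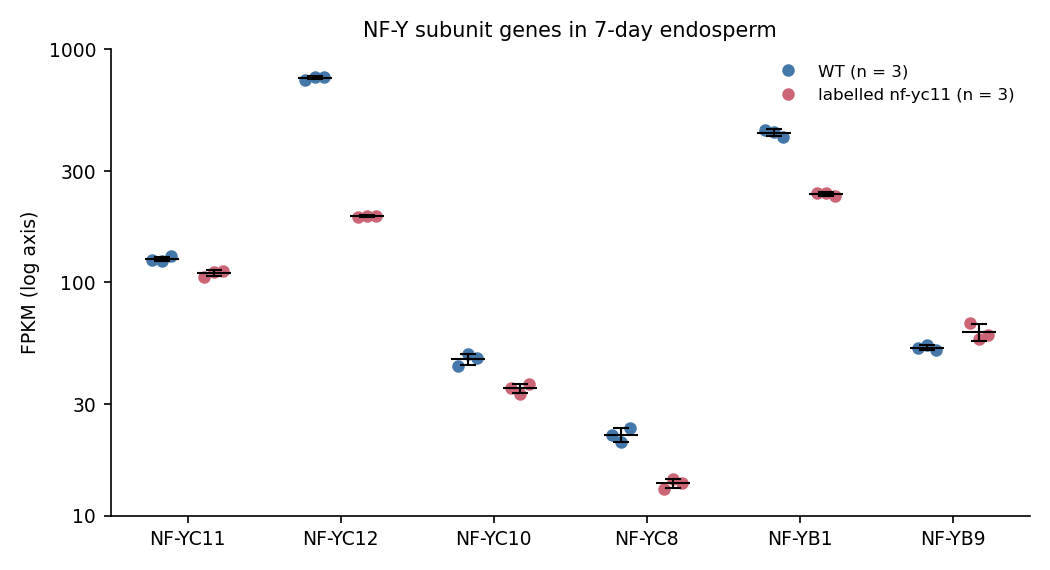
FPKM (log axis) of 6 NF-Y subunit genes in each of the 3 WT and 3 nf-yc11 libraries (points), with the group mean and SD (bars). NF-YC12 fell from 755 to 192 FPKM, NF-YC11 from 126 to 110 FPKM.

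Starch synthesis genes were lower in the libraries labelled nf-yc11. Of 31 measured, 24 fell, 1 rose and 6 did not pass the test, with a median log2 change of −0.46 (adjusted p = 2.5e-11, camera in limma, and adjusted p = 0.0582 with an estimated correlation). AGPS2, a small subunit of ADP-glucose pyrophosphorylase, which makes the glucose donor of starch, fell 3.5-fold from 473 ± 5.78 to 135 ± 12.8 FPKM (SD, n = 3 here and below). The branching enzyme gene BEIIa fell 2.81-fold, from 71.3 ± 1.17 to 25.4 ± 2.16 FPKM, and the starch synthase gene SSIIIa fell 2.74-fold, from 69.5 ± 1.11 to 25.3 ± 1.54 FPKM. GBSSI, which makes amylose, fell 1.75-fold from 1063 ± 19.5 to 608 ± 26.4 FPKM. Pullulanase (PUL) fell 2.06-fold and the plastidial starch phosphorylase PHOL 1.74-fold. FLO4, a pyruvate orthophosphate dikinase and the most abundant member, fell 1.6-fold from 3429 ± 25.5 to 2146 ± 41.0 FPKM. The only member that rose was BEIIb, the main branching enzyme of amylopectin in endosperm, from 1619 ± 27.6 to 2132 ± 47.7 FPKM (log2 change 0.40 ± 0.03, adjusted p = 5.65e-05, limma).

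**Figure D2:**
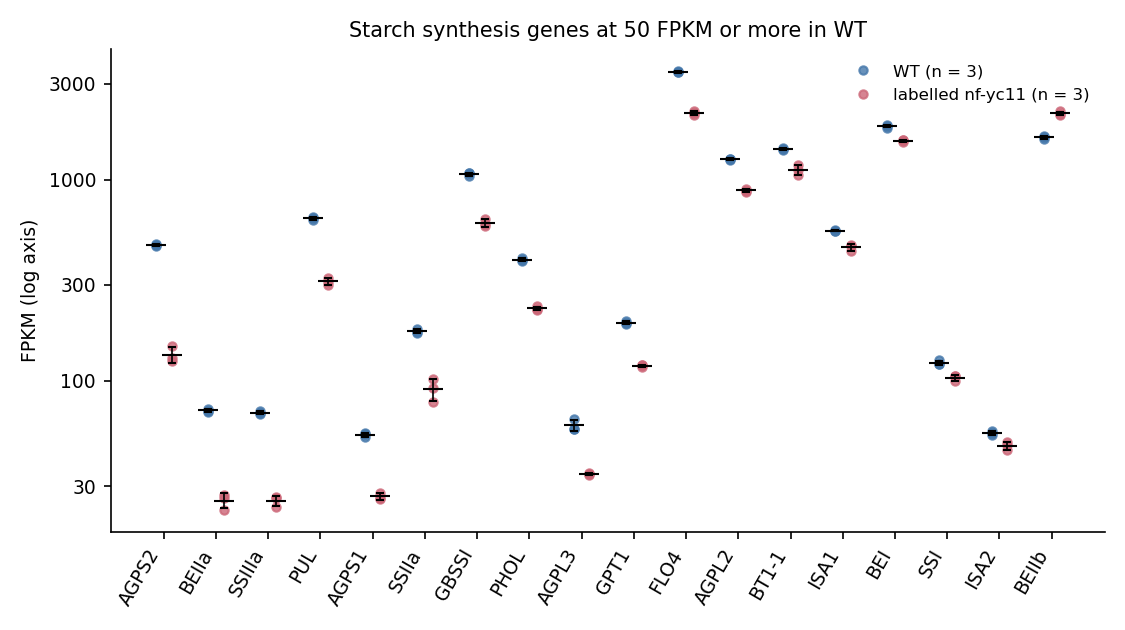
FPKM (log axis) of the 18 starch synthesis genes with a mean of at least 50 FPKM in WT, for each of 3 WT and 3 nf-yc11 libraries (points), with mean and SD (bars), ordered by log2 change. AGPS2, at the left, fell from 473 to 135 FPKM, and BEIIb, at the right, rose from 1619 to 2132 FPKM.

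Genes of sucrose transport and cleavage went both ways. Of 13 measured, 7 rose, 2 fell and 4 did not pass, with a median log2 change of 0.29 that did not pass the list test (adjusted p = 0.14, camera in limma). The sugar exporters SWEET11 (375.9 ± 1.71 to 505 ± 9.01 FPKM) and SWEET15 (30.5 ± 1.62 to 50.3 ± 1.19 FPKM) rose, as did sucrose synthase SUS1, 2.19-fold from 6.44 ± 0.139 to 14.1 ± 1.3 FPKM. UGP1, a UDP-glucose pyrophosphorylase, fell 3.93-fold from 80.8 ± 1.59 to 20.5 ± 0.481 FPKM.

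All 10 glutelin genes kept in the list were lower (median log2 change −0.59, adjusted p = 1.34e-10, camera in limma, and adjusted p = 0.0582 with an estimated correlation). Glutelins are the main storage proteins of the rice grain. For 7 of the 10 the symbol was found in place in the gene table, and GluB1a, GluB1b and GluB6 were not in it. Their joint share of summed FPKM fell from 6.7% ± 0.0882 to 4.89% ± 0.028 (SD, n = 3), and the medians under other scalings were −0.66, −0.66 and −0.45. GluB1a fell 2.44-fold from 695 ± 40.8 to 285 ± 18.5 FPKM, and GluB6 and GluD1 fell 2.41-fold and 2.36-fold. The most abundant member, GluA1, fell 1.17-fold from 15730 ± 190.0 to 13400 ± 129 FPKM. GluA2 fell by 0.21 on the log2 scale, and its call ended under quantile normalization (adjusted p = 0.224, limma). The feature first listed as the globulin Glb1 (OS05G0499100) was left out of the list by the name check, and it rose from 41360 ± 509 to 49190 ± 151 FPKM.

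Of 7 prolamin genes, which encode alcohol-soluble storage proteins, 5 fell and 2 did not pass (median log2 change −0.44, adjusted p = 0.00212, camera in limma, and adjusted p = 0.235 with an estimated correlation). RP10, the most abundant, fell 1.37-fold from 28330 ± 520 to 20740 ± 990 FPKM, and RP14b fell 1.56-fold. RP13b (log2 change 0.01 ± 0.04) and RP13c (0.01 ± 0.04) did not pass, and their directions depended on the scaling: under quantile normalization RP13b moved by 0.28 and RP13c by −0.26. RP13a went from 14.2 ± 12.8 to 0.334 ± 0.3 FPKM, with WT libraries at 4.50, 28.7 and 9.26 FPKM. Glutelin and prolamin genes have near-identical copies, so how the authors' counting split reads among them is uncertain for single members. The only member in the list of seed allergens, RAG1, fell 1.23-fold from 7593 ± 180 to 6156 ± 144 FPKM, and a list of 1 was not tested.

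Among 11 genes of protein folding in the endoplasmic reticulum, 5 fell, 2 rose and 4 did not pass, and the list did not pass its test (median log2 change −0.06, adjusted p = 0.0877, camera in limma). With size factors, TMM factors or quantile normalization it did, with adjusted p of 0.0337, 0.0332 and 0.0106. PDIL1-1, a protein disulfide isomerase, fell from 2335 ± 35.6 to 1748 ± 46.1 FPKM. The thiol oxidase gene ERO1 rose from 72.8 ± 5.13 to 96.3 ± 3.66 FPKM and calreticulin (CRT) from 234 ± 2.94 to 277 ± 8.16 FPKM.

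Of 12 endosperm transcription factor genes, 8 fell, 2 rose and 2 did not pass (median log2 change −0.30, adjusted p = 0.00141, camera in limma, and adjusted p = 0.0582 with an estimated correlation). NAC20 fell 1.59-fold from 447 ± 3.28 to 281 ± 12.6 FPKM, and MADS7 1.52-fold from 200.3 ± 2.63 to 132 ± 9.99 FPKM. bHLH144 fell from 55.9 ± 0.376 to 43.5 ± 3.18 FPKM. RPBF, a Dof-type activator of storage protein genes and the most abundant of the list, stood at 543 ± 4.07 and 539 ± 25.3 FPKM and did not pass (adjusted p = 0.814, limma), except under quantile normalization (log2 change −0.13) and with the total taken without the 100 most abundant genes (−0.12). RSR1, an AP2-type factor known to act on starch synthesis genes, rose from 12.9 ± 0.405 to 16.5 ± 1.03 FPKM.

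Among 7 nitrogen assimilation and amino acid genes, 5 fell, 1 rose and 1 did not pass (median log2 change −0.14, adjusted p = 0.0303, camera in limma, and adjusted p = 0.143 with an estimated correlation). The list call also ended without WT replicate 1 (0.0941) or WT replicate 2 (0.0875). The cytosolic glutamine synthetase GS1;3 fell 1.73-fold, from 96.6 ± 3.25 to 55.9 ± 1.47 FPKM, and the alanine aminotransferase AlaAT1 fell from 1596 ± 41.4 to 1251 ± 35.1 FPKM. NADH-GOGAT1, a glutamate synthase, rose 1.69-fold from 47.6 ± 3.09 to 80.5 ± 5.12 FPKM.

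Heat shock protein genes were higher in the libraries labelled nf-yc11. Of 7 measured, 5 rose, none fell and 2 did not pass, with a median log2 change of 0.73 (adjusted p = 0.00141, camera in limma, and adjusted p = 0.0582 with an estimated correlation). The small heat shock proteins HSP17.7, HSP24.1 and HSP17.4 rose 5.11-fold, 3.07-fold and 2.94-fold, HSP24.1 from 25.6 ± 0.842 to 78.4 ± 1.84 FPKM. HSP82A, of the HSP90 family, rose 1.67-fold. HSP16.9A, the most abundant member, was at 157 ± 8.24 and 167 ± 7.57 FPKM and did not pass (adjusted p = 0.164, limma).

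Of 6 cell cycle and DNA replication genes, 2 rose, 1 fell and 3 did not pass, and the list did not pass (adjusted p = 0.88, camera in limma). Its median log2 change was −0.02, its mean was 0.01, and camera and fry differed in sign. PCNA, the sliding clamp of DNA replication, rose from 54.2 ± 1.85 to 68.2 ± 1.54 FPKM. CDKB1;1, a cyclin-dependent kinase gene, rose from 26.5 ± 1.52 to 30.9 ± 2.09 FPKM, but this call ended under each scaling (adjusted p 0.115 to 0.132, limma) and without the variance trend (0.0509). It also ended without WT replicate 2 (0.094), WT replicate 3 (0.0839), nf-yc11 replicate 2 (0.0618) or nf-yc11 replicate 3 (0.0874). The cyclin gene CYCB1;1 fell from 6.31 ± 0.0555 to 4.81 ± 0.625 FPKM, and without WT replicate 1, 2 or 3 its adjusted p was 0.0581, 0.0546 or 0.0577 (limma).

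Markers of other parts of the seed were measured beside these groups. Of 7 embryo and aleurone markers, 5 fell, 1 rose and 1 did not pass, and the list did not pass (median log2 change −0.11, adjusted p = 0.126, camera in limma) except under quantile normalization (0.0229), with the gene length trend removed (0.0157) and with fry (0.0411). The oleosin gene OLE16 rose from 2025 ± 13.4 to 2583 ± 118 FPKM, whereas OLE18 was at 2302 ± 158 and 2442 ± 84.8 FPKM and did not pass. Among the 5 that fell, RAB21 went from 252.3 ± 5.6 to 227 ± 1.24 FPKM and LEA3 from 114.8 ± 2.42 to 103.7 ± 1.81 FPKM. Photosynthesis genes, active in the green maternal pericarp, had 11 members lower, 1 higher and 5 not called of 17 (median log2 change −0.29, adjusted p = 0.000103, camera in limma, and adjusted p = 0.143 with an estimated correlation). LHCB1 (CAB1R) fell 1.61-fold from 438 ± 3.82 to 272 ± 7.14 FPKM and LHCA4 fell 1.47-fold, both encoding light-harvesting proteins. The most abundant member, LHCB1 (CAB2R), was at 1107 ± 12.6 and 1143 ± 67.2 FPKM and did not pass (adjusted p = 0.43, limma). LHCB6 alone rose (log2 change 0.39), and its call ended under each scaling, with adjusted p of 0.0572 to 0.0602 (limma), with no filter on low values (0.0545), and without WT replicate 1 (0.074), 2 (0.0754) or 3 (0.0515). In each of the lists, the counts adjusted over the list alone were the same as those over all genes.

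**Figure D3:**
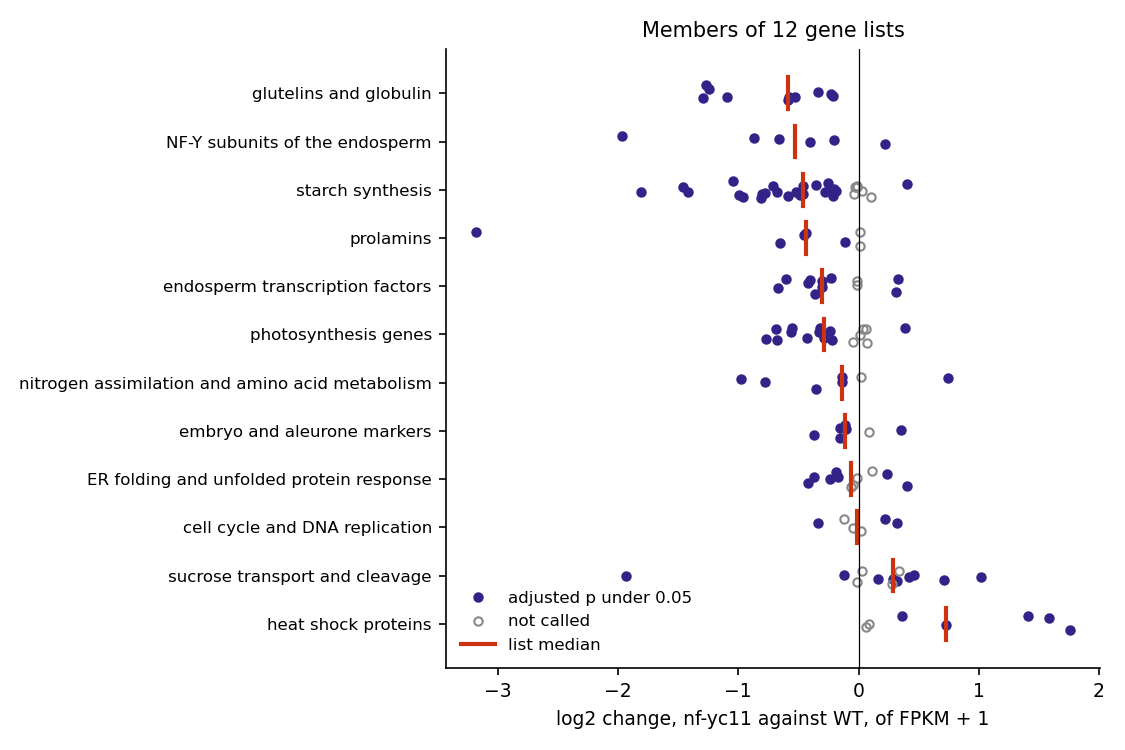
The log2 change of FPKM + 1 (nf-yc11 against WT, 3 libraries each) for every tested member of 12 gene lists (points, filled where the limma adjusted p was under 0.05), with each list's median (bar). Glutelin genes had the lowest median, −0.59, and heat shock genes the highest, 0.73.

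Across 22093 features with a mean of at least 1 FPKM, 10842 (49.1%) changed at an adjusted p under 0.05 (limma), 6586 higher and 4256 lower in the libraries labelled nf-yc11. Most changes were small, with a median absolute log2 change of 0.45, and 504 features rose and 485 fell at least 2-fold. The split between directions depended on the scaling. It was 5434 higher and 5295 lower with size factors, 5411 and 5313 with TMM factors, and 5403 and 5273 with quantile normalization. With the total taken without the 100 most abundant genes it was 4997 and 5749, and with a trend on gene length removed 5063 and 5174, both chosen after seeing the data. These scalings moved the median log2 change of all features by −0.064 to −0.058, and the total without the 100 most abundant genes moved it by −0.089. Of the features without a symbol that met the naming rule, those with the largest rises on the log2(FPKM + 1) scale were Novel00754, from 0.521 ± 0.0194 to 537 ± 221 FPKM with nf-yc11 libraries between 304 and 742, and OS02G0216400, from 0.685 ± 0.196 to 61.0 ± 6.66 FPKM. The order of such features depends on the pseudocount. The largest falls on that scale were those of OS10G0381601, from 73.1 ± 1.18 to 0.283 ± 0.0974 FPKM, and OS01G0537250, from 131 ± 24.4 to 2.03 ± 0.293 FPKM.

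The libraries of a group were alike, with Pearson r of log2 values across genes of 0.981 to 0.983 within groups and 0.948 to 0.955 between them. The labels do not say that replicates came from separate plants, so the p-values measure only the spread between these libraries, which may be technical. Above counting noise the coefficient of variation, as a median over genes with many reads, was 0.681% in WT and 2.56% in nf-yc11. With 3 libraries such a median runs low, and it leaves out the genes that varied more. Between pairs of WT libraries 10.8% to 13.6% of genes lay beyond the 95% limit of counting noise, and between pairs of nf-yc11 libraries 13.7% to 20.2%.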

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

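Tests with voom on the recovered reads, RAP gene IDs only, the total without the 100 most abundant genes, the gene length trend removed and other list members were chosen after seeing the data. The count of changed features ranged from 8320 (at least 5 FPKM) to 11694 (voom, of which 10504 were also called with FPKM values), and from 9075 to 9686 when 1 library was left out. A 2-fold minimum left 989 (504 higher, 485 lower), by its construction. The deviations of same-numbered libraries correlated at −0.05, 0.004 and −0.048, against −0.057 to 0.109 for different numbers. No shared deviation was seen, but this cannot tell whether the libraries were prepared in pairs. The replicate block gave 9948 changed features and 8 lists and ended the call of CDKB1;1 (adjusted p = 0.0664, limma). With an estimated correlation 0 lists were called: adjusted p (camera in limma) was 0.0582 for the NF-Y, starch, glutelin, transcription factor and heat shock lists, 0.235 for prolamins, and 0.143 for nitrogen and photosynthesis genes. The estimated correlations of the NF-Y, transcription factor and heat shock lists were −0.13, −0.03 and −0.02, below the preset 0.01. A stronger correlation between genes therefore did not end these calls. Their adjusted p of 0.0582 came from another, untested part of that form of camera and does not measure correlation between their genes. Those of the starch, glutelin, photosynthesis and prolamin lists were 0.12, 0.18, 0.16 and 0.67. The nitrogen list ended at 0.0833 with at least 5 FPKM and 0.0504 without the variance trend, and ranged from 0.0222 to 0.0941 when 1 library was left out. The endoplasmic reticulum list passed with size factors (0.0337), TMM factors (0.0332), quantile normalization (0.0106), the total without the 100 most abundant genes (0.0242) and fry (0.00155). The embryo and aleurone list passed with quantile normalization (0.0229), the length trend removed (0.0157) and fry (0.0411). With only members checked in the gene table, 5 of 8 lists were called. Among these 8 none lost its call, and the sucrose list, without UGP1, passed at 0.0488. The NF-Y, prolamin, nitrogen and photosynthesis lists kept too few members to test. Why list calls changed was not tested. Of 1406 values of the 79 genes chosen for naming, 1368 kept their side of the threshold, 32 lost the call and 3 gained it with the same sign. Among these 79 genes, none called with the first settings turned its direction, whereas 6 not called there turned sign, in 26 values, of which 3 passed the test: RP13c was at −0.26 under quantile normalization, and RP13b at −0.20 and RP13c at −0.21 with the length trend removed. Over all features, 9643 of 9647 called in both fits had the same direction under quantile normalization and 8737 of 8747 with the length trend removed. The planned count-based tests were not run, and voom on recovered reads replaced them. Depth limits low genes: 3 reads on 1500 bases were 0.091 to 0.137 FPKM.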

Other observations

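The test of added tissue and the pair count without glutelin IDs were chosen after the results were seen. Features outside the RAP gene IDs also differed between the groups. Those with EPlOSAG IDs held 3.21% ± 0.0962 (SD, n = 3) of summed FPKM in WT and 2.18% ± 0.136 in the libraries labelled nf-yc11 (exact permutation p = 0.1, two-sided, the smallest that 3 against 3 allows). Of 1446 tested, 129 rose and 271 fell (limma). Of the 1082 tested features of the class of Novel00754, 402 rose and 142 fell, and their share went from 0.879% ± 0.00755 to 1.12% ± 0.0332 (exact permutation p = 0.1).

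More features were called higher than lower, 60.7% of the changed ones. Of the 100 most abundant features, 45 were called higher and 35 lower. Together they held 43% of summed FPKM in WT and 40.5% in nf-yc11, so the total that FPKM values share may raise the rest. That total is one of reads, however, and the share of these features in the reads was not measured. Summed FPKM itself was 925222 to 930439 in the WT libraries and 950463 to 963395 in the nf-yc11 libraries. Values rescaled to the total without those features gave 46.5% higher calls, but any factor that lowers every value of the nf-yc11 libraries lowers this share, so the test does not decide and the explanation stays open. The number of changed features, 10842, was above the 1 feature of the highest other split, and the number of lists called, 8, was above 3. Every other split mixes libraries of both labels, so a difference between the labels widens the spread within its groups and lowers its counts. The real split is 1 of 10, and 10 splits are too few for a share under 0.05.

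Starch synthesis and glutelin genes were lower, with medians of −0.46 and −0.59. Scaling between libraries is argued against as the whole cause, since the highest of their medians under 3 scalings was −0.45, and so is gene length, since the highest with the length trend removed was −0.40. Added pericarp or embryo tissue would lower glutelins, made in endosperm, by 1 factor, but their log2 changes ran from −1.29 to −0.21, with an SD of 0.44 against a median SE of 0.02. This argues against added tissue as the whole cause of the glutelin falls, but it cannot exclude a part that all of them share. The starch synthesis genes were not in this test. The photosynthesis list was at −0.29 (95% bootstrap interval over members −0.55 to 0.01) and the embryo and aleurone list at −0.11 (−0.15 to 0.09), and since both intervals reach above 0, these lists alone, examined first, left added tissue open. An effect of the genotype named by the labels is a hypothesis that stays open beside untested differences such as the stage of the grains at harvest.

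Features changed at least 2-fold lay next to each other more often than by shuffling. Among 19560 RAP gene IDs in order along the chromosomes, 41 neighbouring pairs were both changed, against a mean of 20.1 and a 95th percentile of 27 in 10000 shuffles within chromosomes (one-sided permutation p = 1e-04, the smallest they can give). Of these pairs, 32 moved in the same direction. The share of tested RAP gene IDs changed at least 2-fold ran from 2.45% (chromosomes 8 and 11) to 3.86% (chromosome 4). No whole chromosome stood far apart, though short segments would not show in these shares. The densest stretch, on chromosome 2, had 6 of 10 neighbours changed, 4 of them glutelin IDs, and without the glutelin and globulin IDs 38 pairs were left (95th percentile 27). Chromosome segments that differ between the lines are a candidate explanation, and tandem copies that change together, which were not tested, might give the same count.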
